A study of Homo sapiens with 8 samples.

How the data were processed

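Gene expression was measured by Affymetrix arrays in NB4 cells, a human acute promyelocytic leukaemia line, after lentiviral transduction at a multiplicity of infection of 10. A scrambled control or 1 of 3 CDK2 hairpins (shCDK2 #1, #3 and #10) was used, and RNA was taken after 2 days, given as an early differentiation stage, or 5 days, given as a late one. There were 8 arrays, 1 per construct and day, each labelled from 6 micrograms of total RNA. The authors deposited log2 signals for 49395 probe sets. The labels name Partek; its version and the normalization method are not given in the sources used here. That the values are log2 was inferred from their range. Array medians lay between 6.30 and 6.43 log2 and standard deviations between 2.14 and 2.26, so the distributions were not identical, with the lowest median and the highest standard deviation in #3 at day 5. The bioB spike-in mean lay between 8.67 and 9.37 log2. No pair of arrays was identical. The number of arrays limits the precision.

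Of the probe sets, 44994 had 1 gene in the annotation, 1832 had several and 2569 had none, 102 control probe sets among them. Symbols were updated by Entrez gene ID in a RefSeq gene table, which held 44967 of the probe sets of 1 gene and lacked 27. Each gene was taken from its probe set with the highest mean over the 8 arrays, among probe sets of 1 gene. Of 18132 genes, 12845 with a mean above the 40th percentile of all probe sets (5.83 log2) were tested. A tested gene could lie under this value in the scramble arrays, and no measure of background was used here. Values were used as deposited.

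Fits used limma 3.58.1 in R 4.3.3, with tables handled by the data.table package (version 1.17.8), empirical Bayes moderation and Benjamini-Hochberg adjusted p under 0.05. The hairpins served as the repeats of the knockdown, and the lone scramble array of a day was assumed to vary as hairpin arrays do. A fit with a mean per group and day (4 residual degrees of freedom, prior 3.13) gave the knockdown at each day, day 5 against day 2 in each arm, and the difference of the knockdown changes. The knockdown over both days came from construct means (2 residual degrees of freedom, prior 3.64). Each hairpin was set against scramble with construct and day as terms (3 residual degrees of freedom, prior 4.54). These hairpin comparisons share the scramble arrays, so overlaps between them were not counted. All limma tests were two-sided.

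On simulated data of the same size, with 200 of 12845 genes changed in each of 5 simulations, the fit for day 2 recovered 2.4% of changes of 1 log2, 72.8% of 2 and 92% of 3. For both days the shares were 2.8%, 76.8% and 95.2%, for each hairpin 27.6%, 94% and 97.2%, and for day 5 against day 2 they were 39.2%, 88% and 98%. False calls per simulation were 7.6, 6.6, 8 and 8.6. The changed genes were picked at random and moved alike in every array of the changed group. In the data the hairpins differed, as for ZFP36L1 at day 2 (2.82 log2, SE 2.08), and that difference enters the spread. The shares therefore do not hold for changes that differ between hairpins.

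The 19 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. They were granulocyte maturation; promyelocyte and progenitor; monocyte and macrophage; E2F and DNA replication; G2/M and mitosis; CDKs, cyclins and CDK inhibitors; p53 targets; interferon response; NF-kB and inflammatory cytokines; peroxiredoxins and redox; integrated stress and unfolded protein response; cholesterol biosynthesis; apoptosis regulators; glycolysis; erythroid and megakaryocyte; lymphoid; eosinophil, basophil and mast cell; fibroblast and epithelial; and heat shock. Where several lists follow in a sentence, each bracket gives the median, the adjusted p with the preset correlation and then that with an estimated correlation. No list passed with an estimated correlation in any comparison. Fry passed only in hairpins #3 and #10. The lymphoid, erythroid and megakaryocyte, and fibroblast and epithelial lists were the dimmest, with median signals of 6.90, 6.98 and 6.67 log2. Array medians were 6.30 to 6.43, so small changes of these lists cannot be told apart from a shift of dim genes.

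The groups, comparisons, lists, alternatives and the rule for naming genes were set before the data were examined. In the pooled knockdown comparisons and in day 5 against day 2, the rule took CDK2 and, per direction, the 10 called genes with the largest change and 1 sign in every hairpin. Symbols of uncharacterized loci, antisense transcripts and open reading frames were passed over. Places left over went to the genes whose least-moved hairpin moved most, and from each list up to 4 members with the largest mean change were named. Lists in each hairpin, differences between hairpins and a list of hypoxia-inducible genes were added after the data were seen.

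Alternatives were quantile normalization, median centring, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust, a 2-fold minimum, the construct as a replicate block, the arrays of a day alone, and leaving out each hairpin. Leaving out the array labelled shCDK2 #3 at day 2 or the array labelled scramble at day 5, in which CDK2 was near scramble and low for a control, was added later, as was leaving out both for the knockdown over both days. For the knockdown at day 5 the array labelled scramble at day 5 was replaced by scramble at day 2, since that day has no other control. An alternative for linear values was not needed. No array was left out of the main results. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.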

Results

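CDK2, the cyclin-dependent kinase targeted by the hairpins, was measured by 3 probe sets in each of the 8 arrays of NB4 cells, an acute promyelocytic leukaemia line. On the probe set with the highest mean, which stands for the gene, the log2 signal at day 2 was 9.10 in scramble, 7.78 in shCDK2 #1 and 7.54 in shCDK2 #10. It was 9.03 in the array labelled shCDK2 #3 at day 2. At day 5 the signal was 8.19 in the array labelled scramble at day 5, 7.89 in shCDK2 #1, 7.72 in shCDK2 #3 and 8.08 in shCDK2 #10. As a share of the scramble array of the same day, CDK2 stood at 39.9% in #1, 95% in the array labelled shCDK2 #3 at day 2 and 34.0% in #10. At day 5 the shares were 81.1% in #1, 72.3% in #3 and 92.9% in #10.

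**Figure D1:**
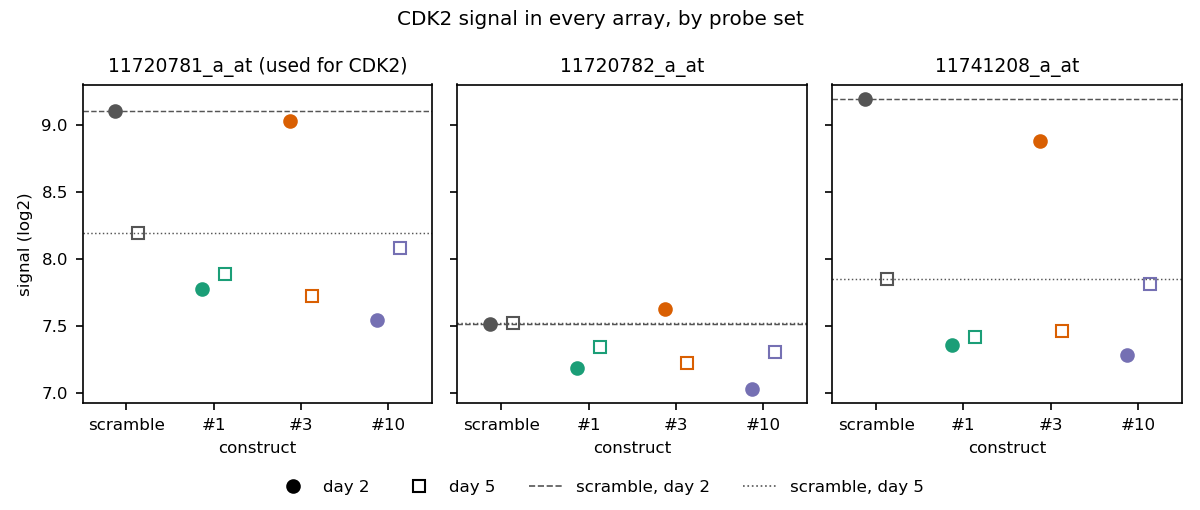
Log2 signal (vertical axis) of the 3 CDK2 probe sets in each construct (horizontal axis), with filled circles for day 2, open squares for day 5 and lines at the scramble arrays. On the probe set that stands for CDK2, the array labelled shCDK2 #3 at day 2 lay at 9.03, near the 9.10 of scramble at day 2, and the array labelled scramble at day 5 lay at 8.19.

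On a further CDK2 probe set, with 9.19 in scramble at day 2, the shares at day 2 were 28.1% in #1, 80.5% in the array labelled shCDK2 #3 at day 2 and 26.6% in #10, and at day 5 they were 74.0% in #1 and 76.4% in #3. Its signal in #10 at day 5 was 7.81, against 7.85 in the array labelled scramble at day 5. On the dimmest CDK2 probe set, with 7.51 in scramble at day 2, the shares were 79.7%, 108% and 71.7% at day 2 and 88.1%, 81.2% and 85.7% at day 5. The array labelled scramble at day 5 carried 53.2%, 39.5% and 101% of the signal of scramble at day 2 on these probe sets, in the order given. CDK2 was thus near its scramble level in the array labelled shCDK2 #3 at day 2 and low for a control in the array labelled scramble at day 5, so directions drawn from either array carry that doubt. In limma, CDK2 was lower in shCDK2 by -0.99 log2 at day 2 (SE 0.53, 95% confidence interval -2.24 to 0.27, adjusted p = 1.00, 3 hairpin arrays and 1 scramble array). The values were -0.29 at day 5 (SE 0.53, adjusted p = 0.921) and -0.64 over both days (SE 0.29, interval -1.35 to 0.07, adjusted p = 1.00). With both days as repeats of a hairpin, CDK2 stood at -0.81 in #1, -0.27 in #3 and -0.83 in #10 (SE 0.42 each, adjusted p = 1.00, 0.814 and 0.321). None of these passed. The labels do not say that arrays came from separate cultures, so the p-values measure only the spread between these samples.

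Hairpin #10 gave the most called genes against scramble. The Fc receptor gene FCGR2B rose by 5.38 log2 (SE 0.58, adjusted p = 0.015), the protease inhibitor gene SERPINA1 by 5.32 (SE 0.87), and ZFP36L1, which encodes an RNA-binding protein that promotes mRNA decay, by 5.27 (SE 0.64). The lectin gene CLEC2B rose by 4.40, the death ligand gene TNFSF10 by 4.04, the adhesion scaffold gene NEDD9 by 3.88, the co-receptor gene NRP1 by 3.71, SPAG4 by 3.67, the activation marker gene CD69 by 3.66 and the transcriptional repressor gene BHLHE41 by 3.53. In scramble CLEC2B (4.22 and 4.99), NEDD9 (5.33 and 4.74) and SPAG4 (4.88 and 5.33) lay under the 5.83 log2 that a gene's mean over all arrays had to exceed, so the size and rank of these rises are uncertain. The iron-binding nuclear protein gene PIR fell by 2.08 (SE 0.26, adjusted p = 0.017). GRWD1, UTP20 and RRP15, each known for a part in ribosome assembly, fell as well, by -1.45, -1.39 and -1.29. FOXM1, a transcription factor of the mitotic programme, had a change of -1.39, and GFM1, a mitochondrial elongation factor gene, one of -1.31. ZNF726 stood at -1.28, NACC2 at -1.27, the mitochondrial carrier gene SLC25A10 at -1.25 and the RNA-modifying enzyme gene PUSL1 at -1.24, and these 4 also passed. All 20 had the same sign in both #10 arrays, and these names by hairpin were chosen after their values were seen.

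In shCDK2 #10, limma called 258 of 12845 genes, 217 higher and 41 lower, and 2599 had an unadjusted p under 0.05 (chance gives 642). The 2 days of a construct stood in as its repeats, with 1 array each. The p-values thus measure how changes differed between days, not a spread between separate cultures of #10. That spread was pooled over scramble and all hairpins, so FCGR2B had an SE of 0.58 in #3 as well as in #10. The calls in #10 therefore depend on the arrays of the other constructs too. The split by direction leans on the scaling, since 84.1% of called genes were higher with the values as deposited, 78.7% of 367 after quantile normalization and 97.6% of 82 after median centring. The count was 354 without hairpin #1, 960 without hairpin #3, 960 without the array labelled shCDK2 #3 at day 2 and 0 without the array labelled scramble at day 5, which leaves scramble with 1 array. Without that last array FCGR2B stood at 4.84 and PIR at -2.35, each with adjusted p = 0.187. The same array ended the calls of p53 targets (median 0.31), stress response genes (0.13) and apoptosis regulators (0.13) when left out, and lymphoid genes passed without it (0.17). After median centring 12 of the 20 named genes did not pass, among them FOXM1 at -1.36 (adjusted p = 0.061), TNFSF10 at 4.07 (0.073) and SERPINA1 at 5.35 (0.067). RRP15 did not pass after quantile normalization (-1.25, adjusted p = 0.056), nor did TNFSF10 (3.87, 0.053), GRWD1 (-1.41, 0.053) and NACC2 (-0.77, 0.066) with the mean of a gene's probe sets.

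Genes of the E2F and DNA replication list fell in hairpin #10 (median -0.49 log2, 42 of 46 lower; camera with a preset correlation, adjusted p = 4.88e-10, adjusted p = 0.183 with an estimated correlation). The phosphatase gene CDC25A, with a change of -1.19 (SE 0.22, adjusted p = 0.047), and the replication helicase gene CDC45, with -0.92 (SE 0.17, adjusted p = 0.047), were its 2 members past the threshold over all genes. Adjusted over the list alone, 18 members were lower. Genes of G2/M and mitosis fell too (median -0.46, 49 of 50 lower, adjusted p = 4.88e-10, adjusted p = 0.254 with an estimated correlation), FOXM1 by -1.39 and the cyclin gene CCNA2 by -1.14 over all genes. Of these genes, 9 passed adjusted over the list alone. Among CDKs, cyclins and CDK inhibitors the median was 0.00 (adjusted p = 0.118), and CDKN1A, the gene of the CDK inhibitor p21, rose by 2.52 (SE 0.34, adjusted p = 0.022), as the single member called either way. CDKN1A and BBC3, a pro-apoptotic gene with a rise of 1.15, were the p53 targets past the threshold (median 0.29, adjusted p = 0.0074, adjusted p = 0.254 with an estimated correlation), and 6 higher and 2 lower members passed adjusted over the list alone.

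Interferon response genes rose in hairpin #10 by a median of 1.82 (33 of 34 higher, adjusted p = 6.51e-18, adjusted p = 0.254 with an estimated correlation). The RNA sensor gene IFIH1, at 2.44 (SE 0.43), and BST2, at 2.47, passed over all genes, and 27 members passed adjusted over the list alone. IFIT1 stood at 4.06 (SE 1.02, adjusted p = 0.086) and IFIT2 at 3.92 (SE 1.11, adjusted p = 0.109), and neither passed. NF-kB and inflammatory cytokine genes rose by a median of 1.51 (21 of 24 higher, adjusted p = 6.6e-10, adjusted p = 0.254 with an estimated correlation), with the feedback inhibitor gene TNFAIP3 at 2.27 (SE 0.41, adjusted p = 0.046) past the threshold over all genes and 12 adjusted over the list alone. The cytokine genes IL1B, at 4.85 (SE 1.14, adjusted p = 0.077), and CCL3, at 4.65 (SE 0.91, adjusted p = 0.051), did not pass. Granulocyte maturation genes rose (median 0.34, 22 of 29 higher, adjusted p = 7.92e-05, adjusted p = 0.277 with an estimated correlation). Of these, the gelatinase gene MMP9, at 2.61 (SE 0.47, adjusted p = 0.046), and the antimicrobial peptide gene CAMP, at 1.07, passed over all genes and 9 adjusted over the list alone. The integrin genes ITGAM, at 3.17 (adjusted p = 0.097), and ITGAX, at 2.42 (adjusted p = 0.092), did not. In the monocyte and macrophage list (median 0.46, adjusted p = 0.0018, adjusted p = 0.254 with an estimated correlation), the co-stimulatory gene CD86, at 1.70 (SE 0.24), and CD68, at 1.29, passed, with 3 adjusted over the list alone.

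Glycolysis genes rose in hairpin #10 by a median of 0.28 (16 of 21 higher, adjusted p = 1.69e-07, adjusted p = 0.254 with an estimated correlation). The hexokinase gene HK1 rose by 3.21, the aldolase gene ALDOC by 2.82, the enolase gene ENO2 by 2.45, the regulator gene PFKFB4 by 2.42 and the kinase gene PDK1 by 1.89 over all genes, and 9 passed adjusted over the list alone. Apoptosis regulators (median 0.22, adjusted p = 0.0026, adjusted p = 0.268 with an estimated correlation) had 3 called genes, TNFSF10 and the mitophagy receptor genes BNIP3, at 2.71, and BNIP3L, at 2.73, and 6 adjusted over the list alone. Integrated stress and unfolded protein response genes (median 0.24, adjusted p = 0.0017, adjusted p = 0.369 with an estimated correlation) had the lipoprotein receptor gene VLDLR, at 2.99, and the mTORC1 inhibitor gene DDIT4, at 1.66, and 3 adjusted over the list alone. Eosinophil, basophil and mast cell genes (median 0.83, 6 tested, adjusted p = 0.0018, adjusted p = 0.254 with an estimated correlation) had HDC, at 1.56, and PRG2, at 1.31, and 3 adjusted over the list alone. Heat shock genes fell by a median of -0.45 (14 of 16 lower, adjusted p = 0.0017, adjusted p = 0.254 with an estimated correlation) with 0 called over all genes and 3 lower adjusted over the list alone. Peroxiredoxin and redox genes fell by a median of -0.21 (adjusted p = 0.015, adjusted p = 0.254 with an estimated correlation), with 0 called over all genes and NQO1, a quinone reductase gene at -1.33 (adjusted p = 0.063), adjusted over the list alone. The cholesterol biosynthesis, lymphoid, and fibroblast and epithelial lists did not pass (medians 0.05, -0.05 and -0.02), and each had 1 gene called over all genes: INSIG1 at 1.68, CD3D at 2.25 and ACTA2 at 1.08. Adjusted over the list alone, these lists gave 2, 1 and 1. The erythroid, lymphoid and fibroblast lists had means of 0.21, 0.14 and 0.01, against their medians in sign. The promyelocyte and progenitor list (median -0.26) and the erythroid and megakaryocyte list (median -0.16) did not pass and had 0 called over all genes, with PRTN3 at -1.10 and CD9 at 2.93 adjusted over the list alone. By fry, which tests whether a list's genes move on balance one way, E2F, redox, glycolysis, and eosinophil, basophil and mast cell genes passed in #10 (adjusted p = 0.019, 0.019, 0.021 and 0.024).

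**Figure D2:**
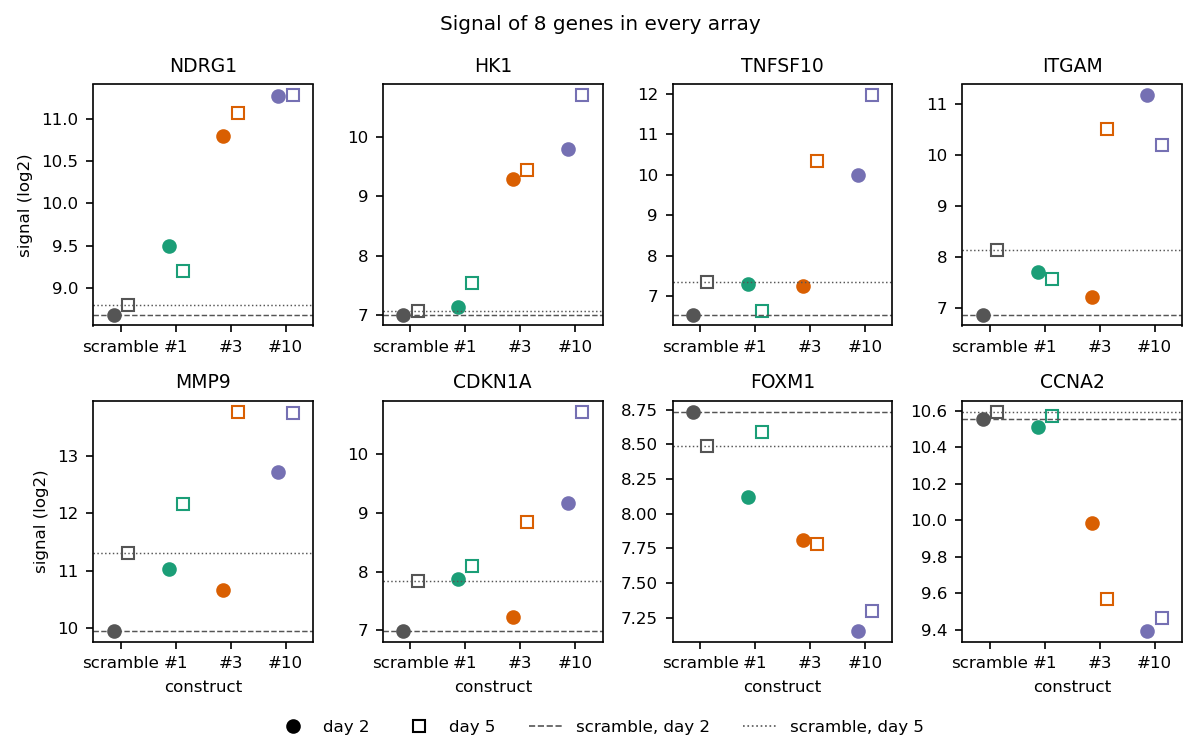
Log2 signal (vertical axes, each with its own range) of 8 genes in each construct (horizontal axes), with filled circles for day 2, open squares for day 5 and lines at the scramble arrays. The genes were chosen after their values were seen; NDRG1 and HK1 were called in shCDK2 #3 and #10, TNFSF10, MMP9, CDKN1A, FOXM1 and CCNA2 in #10, and ITGAM in neither.

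In hairpin #3, 4 genes rose against scramble and 0 fell: ALDOC by 3.02 (SE 0.29, adjusted p = 0.044), HK1 by 2.33 (SE 0.24, adjusted p = 0.047), NDRG1, a stress-responsive gene, by 2.20 (SE 0.20, adjusted p = 0.044) and MXI1, an antagonist of MYC, by 2.14 (SE 0.20, adjusted p = 0.044). These rises were alike in the array labelled shCDK2 #3 at day 2 and in #3 at day 5, for NDRG1 2.12 and 2.28 and for ALDOC 3.08 and 2.95. With the days as repeats, genes alike on both days are the ones most easily called, so this likeness says nothing about the label. FCGR2B, at 2.31 and 4.72 in the #3 arrays, did not pass. Across all tested genes the changes of #3 on the 2 days had an r of 0.21. SPAG4 at 2.72, FCGR2B at 3.52, ZFP36L1 at 3.48, NEDD9 at 3.41, CLEC2B at 2.71 and the tubulin gene TUBA1A at 2.57 came next by their least-moved #3 array and did not pass (adjusted p from 0.092 to 0.212). Of these SPAG4, NEDD9 and CLEC2B were dim in scramble, as given above. The genes lower by most in the least-moved #3 array were P2RY6 at -1.32, PIR at -1.17, TUBB3 at -1.35, MLLT11 at -1.02, NACC2 at -1.11, RBP4 at -1.02, CHI3L1 at -1.21, CYTL1 at -0.98, SNRNP25 at -0.95 and NT5DC2 at -0.93, and none passed. In limma 1216 genes had an unadjusted p under 0.05. The 4 calls became 0 after median centring, with adjusted p = 0.070 for all 4 genes. ALDOC then stood at 3.06, HK1 at 2.38, NDRG1 at 2.25 and MXI1 at 2.19. HK1 alone was lost after quantile normalization (2.27, adjusted p = 0.053). They also became 0 with the mean of a gene's probe sets, where ALDOC stood at 2.66 (adjusted p = 0.073), HK1 at 1.41 (0.099), MXI1 at 1.10 (0.166) and NDRG1 at 0.49 (0.421). The count was 9 without hairpin #1, 27 without hairpin #10 (SPAG4, FCGR2B and CLEC2B passed in each case), 213 without the array labelled shCDK2 #3 at day 2 and 0 without the array labelled scramble at day 5. In the last case ALDOC stood at 2.75, HK1 at 2.12, NDRG1 at 2.26 and MXI1 at 2.18. Each of the counts of 213 and 0 rests on a construct with 1 array. Its spread was assumed to be that of the other constructs.

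By list, hairpin #3 had higher glycolysis genes (median 0.28, 17 of 21 higher, adjusted p = 1.38e-08, adjusted p = 0.255 with an estimated correlation), with ALDOC and HK1 past the threshold over all genes and 7 adjusted over the list alone. Cholesterol biosynthesis genes were higher by a median of 0.43 (adjusted p = 4.74e-06, adjusted p = 0.418 with an estimated correlation), with HMGCS1, a synthase gene of the pathway, at 1.80 and INSIG1 at 1.71 among 5 adjusted over the list alone and 0 over all genes. That list had a median of 0.64 in the array labelled shCDK2 #3 at day 2 and 0.19 in #3 at day 5. NF-kB genes (median 0.77, adjusted p = 1.46e-05, adjusted p = 0.418 with an estimated correlation), interferon genes (0.56, 2.8e-05, 0.479) and stress response genes (0.22, 1.23e-04, 0.418) were higher, with 2, 0 and 2 adjusted over the list alone. Granulocyte maturation genes (0.27, adjusted p = 0.023, adjusted p = 0.479 with an estimated correlation), p53 targets (0.19, 0.026, 0.418), apoptosis regulators (0.04, 0.048, 0.479) and eosinophil, basophil and mast cell genes (0.35, 0.011, 0.366) passed as well, with 0, 2, 2 and 2 adjusted over the list alone. E2F genes were lower (median -0.35, 41 of 46, adjusted p = 4.74e-06, adjusted p = 0.255 with an estimated correlation), as were G2/M genes (-0.18, 0.0043, 0.479), heat shock genes (-0.28, 0.0043, 0.418) and redox genes (-0.18, 0.026, 0.366), with 0 adjusted over each list alone. The other 6 lists did not pass. Without the array labelled scramble at day 5, interferon genes (median 0.18), NF-kB genes (0.16), p53 targets (0.15), stress response genes (0.09) and apoptosis regulators (-0.02) did not pass. Without the array labelled shCDK2 #3 at day 2, cholesterol (0.08), redox (-0.11), heat shock (-0.36) and eosinophil, basophil and mast cell genes (0.66) did not pass, while lymphoid genes (-0.37) and fibroblast and epithelial genes (-0.37) did, on 1 array of #3. By fry, glycolysis and redox genes passed (adjusted p = 0.047 each).

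Hairpin #1 had little change. The genes higher by most in its least-moved array were the lipid droplet gene PLIN2 at 1.12 (SE 0.32), the kinase gene YES1 at 1.11 (SE 0.26), BHLHE41 at 1.05, TMEM245 at 1.03, MMP9 at 0.96, CHST2 at 0.95, JUN at 0.93, C3AR1 at 0.85, DNAJB4 at 0.84 and THBS1 at 1.11. The genes lower by most, ranked alike, were RRP15 at -0.94 (SE 0.25), MRAS at -0.91, UTP3 at -0.80, SMIM10 at -0.79, KBTBD11 at -0.89, CEPT1 at -0.69, ETFRF1 at -0.82, CHML at -0.95, LYSET at -0.89 and FAHD1 at -0.68. None passed in limma: 0 genes were called, 171 had an unadjusted p under 0.05 (chance gives 642), and 0 of 19 lists passed camera, with E2F at -0.05, interferon at 0.12 and glycolysis at 0.03. Without the array labelled shCDK2 #3 at day 2 NF-kB genes passed (0.17), and without the array labelled scramble at day 5 lymphoid genes did (0.20). The difference between hairpins was tested in the same fit, as a comparison chosen after the data were seen. Hairpin #10 differed from #1 in 42 genes, 41 higher and PIR lower, among them FCGR2B at 5.13 (SE 0.58), HK1 at 2.91 (SE 0.24) and NDRG1 at 1.93 (SE 0.20). Hairpin #3 differed from #1 in 0 genes (1541 at an unadjusted p under 0.05) and #10 from #3 in 0 (740). CDK2 itself differed between #10 and #1 by -0.02 log2 (interval -1 to 0.96).

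**Figure D3:**
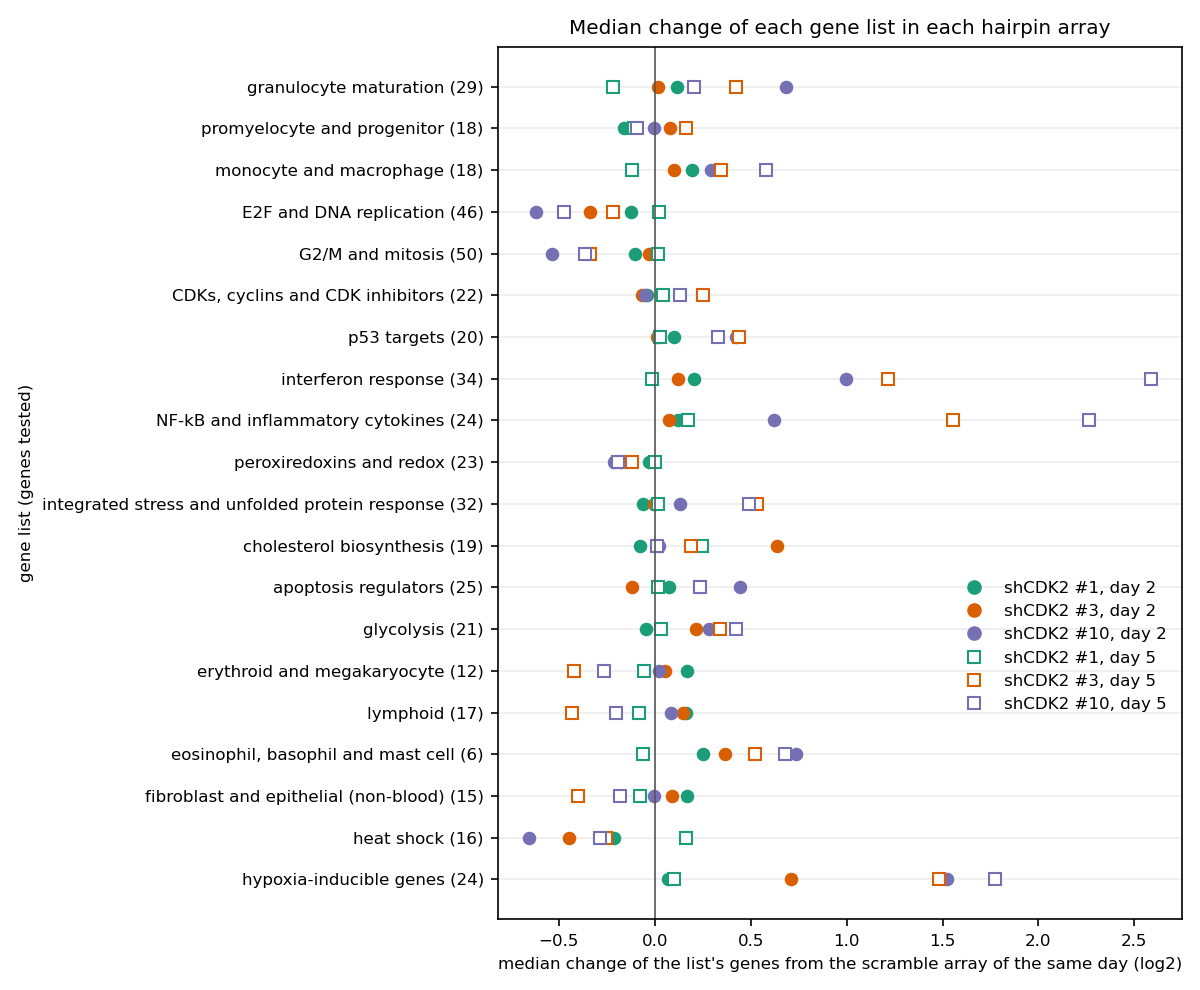
Median log2 change from the scramble array of the same day (horizontal axis) for each gene list (vertical axis, genes tested in brackets), with a colour per hairpin, filled circles for day 2 and open squares for day 5. The interferon median lay at 2.59 in shCDK2 #10 at day 5 and 1.22 in #3 at day 5, and at -0.02 in #1 at day 5; the hypoxia-inducible list was written after the data were seen.

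Counted per array, 105 genes moved at least 2-fold from scramble in shCDK2 #1 at day 2 and 114 at day 5. The number was 247 in the array labelled shCDK2 #3 at day 2 and 840 in #3 at day 5, of which 796 were higher. In #10 it was 1391 at day 2 and 785 at day 5. Hairpin #3 at day 5 also had the lowest bioB spike-in mean of the arrays (8.67, others 9.02 to 9.37) and the highest standard deviation (2.26). In it lymphoid genes stood at -0.43, erythroid and megakaryocyte genes at -0.42 and fibroblast and epithelial genes at -0.40. These dim lists fell by like amounts, and a shift of dim genes in that array was not separated from a change of these genes. Between days, which share no scramble array, the changes of #10 at day 2 and at day 5 had a Pearson r of 0.60 across 12845 genes (covariance 0.248), and those of #10 at day 2 and #3 at day 5 also 0.60. The r was 0.34 for the array labelled shCDK2 #3 at day 2 with #10 at day 5, 0.21 for #3 with itself, 0.15 for #1 at day 2 with #10 at day 5 and -0.07 for #1 with itself. The remaining 3 pairings gave -0.06, -0.00 and -0.11. These are correlations across genes, and genes are not independent replicates.

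At day 2, no gene passed between the 3 hairpin arrays and the scramble array. The genes higher by most in their least-moved hairpin were GBP2, an interferon-induced GTPase gene, at 2.65 (SE 1.93), PPP1R3B, a glycogen-targeting phosphatase subunit gene, at 2.07, CLEC2B at 2.62, the transcriptional repressor gene HBP1 at 2.02 (SE 0.69), SPAG4 at 2.53, PLIN2 at 1.84, ZFP36L1 at 2.82, UBE2L6 at 1.52, CD300A at 2.14 and SHFL at 1.73. Those lower by most were the nucleotide receptor gene P2RY2 at -1.18 (SE 0.33), CHAC2 at -1.40, CLN6 at -1.33, RRP15 at -1.22, FDXACB1 at -1.06, NOL9 at -1.12, DDX19A at -1.12, MOCS3 at -1.08, DLEU2 at -1.77 and the vitamin transporter gene SLC5A6 at -1.37. All of these had 1 sign in the 3 arrays, the array labelled shCDK2 #3 at day 2 included, and none passed (adjusted p = 1.00). In limma 0 genes were called and 442 had an unadjusted p under 0.05 (chance gives 642), 27 higher and 415 lower.

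Cell cycle lists were lower at day 2. E2F genes fell by a median of -0.35 (40 of 46 lower, 28 in every array, adjusted p = 5.29e-06, adjusted p = 0.738 with an estimated correlation), with GINS3 at -0.97 (SE 0.39), CDC25A at -0.96 and FEN1 at -0.80. G2/M genes fell by -0.21 (42 of 50 lower, adjusted p = 0.011, adjusted p = 0.749 with an estimated correlation), with FOXM1 at -1.04 (SE 0.53) and CCNB1 at -0.85, but by -0.03 and past no threshold without hairpin #10. Heat shock genes fell by -0.48 (14 of 16 lower, adjusted p = 3.81e-04, adjusted p = 0.738 with an estimated correlation), with CHORDC1 at -1.13 (SE 0.28), HSPA1B at -0.95 and DNAJB1 at -0.87. Granulocyte maturation genes rose by 0.16 (23 of 29 higher, adjusted p = 0.015, adjusted p = 0.738 with an estimated correlation), with ICAM1 at 1.85 (SE 1.34), ITGAM at 1.81 (SE 1.66) and MMP9 at 1.52, interferon genes by 0.46 (0.038, 0.749) with IRF9 at 1.33, and glycolysis genes by 0.21 (0.038, 0.738) with ALDOC at 1.79 and HK1 at 1.73. Without hairpin #10 these 3 medians were 0.11, 0.18 and 0.13 and none passed. Glycolysis genes, at 0.11, and lymphoid genes, at 0.09, did not pass without the array labelled shCDK2 #3 at day 2 either, and lymphoid genes did not without hairpin #1 (0.12). Without hairpin #1 NF-kB genes passed at 0.22 and redox genes at -0.21. After quantile normalization G2/M genes (-0.14, adjusted p = 0.054), interferon genes (0.50, 0.115) and lymphoid genes (0.09, 0.115) did not pass, and with no filter interferon genes (0.40, 0.080), glycolysis genes (0.21, 0.080) and lymphoid genes (0.09, 0.316) did not. Eosinophil, basophil and mast cell genes (0.48, adjusted p = 0.015, adjusted p = 0.738 with an estimated correlation) and lymphoid genes (0.12, 0.039, 0.738) rose too. The lymphoid list was dim, with a median signal of 6.90 log2, so its small rise may be a shift of dim genes. Cholesterol biosynthesis genes rose by 0.21 (adjusted p = 0.015, adjusted p = 0.738 with an estimated correlation), but their median was -0.05 without the array labelled shCDK2 #3 at day 2. The other 10 lists did not pass, among them promyelocyte and progenitor genes with a median of -0.00, where CEBPA stood at -0.78, and NF-kB genes at 0.21. Apoptosis regulators had a median of -0.02 and a mean of 0.24, and stress response genes a median of 0.03 with a test direction downward. No list had a member called over all genes or adjusted over the list alone.

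At day 5, the 3 hairpin arrays were set against the array labelled scramble at day 5, and no gene passed. The genes higher by most in their least-moved hairpin were CPOX, an enzyme gene of haem synthesis, at 2.40 (SE 0.37), the lysosomal membrane gene SCARB2 at 2.66 (SE 0.99), TUBA1A at 2.70, THBS1 at 2.31, the adenylate kinase gene AK4 at 2.53, GCC2 at 1.77, BNIP3 at 2.44, DYNLT3 at 1.75, BHLHE41 at 2.31 and RNF145 at 1.63. Those lower by most were WIZ at -0.86 (SE 0.29), the defensin gene DEFA5 at -0.97, NACC2 at -1.02, PRICKLE3 at -0.69, GBGT1 at -0.70, TPRN at -0.71, the phosphofructokinase gene PFKM at -0.65, TCTA at -0.81, SH3GL1 at -0.78 and the histone chaperone gene ASF1B at -0.74. The lowest adjusted p in limma was 0.913, with 0 genes called and 171 at an unadjusted p under 0.05 (chance gives 642), 121 higher and 50 lower.

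NF-kB genes rose at day 5 by a median of 1.47 (22 of 24 higher, 19 in every array, adjusted p = 5.84e-12, adjusted p = 0.434 with an estimated correlation), with CCL3 at 3.96 (SE 2.01), IER3 at 3.59 and IL1A at 3.43. Interferon genes rose by 1.35 (33 of 34 higher, 13 in every array, adjusted p = 1.81e-11, adjusted p = 0.488 with an estimated correlation), with IFIT2 at 3.17 (SE 1.91) and IFIT1 at 3.16. The changes of IFIT1 were -0.21 in #1, 3.67 in #3 and 6.00 in #10. Stress response genes rose by 0.32 (adjusted p = 1.54e-05, adjusted p = 0.474 with an estimated correlation), glycolysis genes by 0.24 (1.35e-04, 0.488), apoptosis regulators by 0.22 (0.0045, 0.434), and p53 targets by 0.24 (0.015, 0.434) with GADD45A at 1.45. CDKs, cyclins and CDK inhibitors rose by 0.17 (adjusted p = 0.015, adjusted p = 0.434 with an estimated correlation) with CDKN1A at 1.38 (SE 1.04), but this list had a median of -0.04 and the p53 targets one of -0.01 with the array labelled scramble at day 5 replaced by scramble at day 2. Cholesterol genes passed with a median of 0.02 and a mean of 0.32 (adjusted p = 0.010, adjusted p = 0.614 with an estimated correlation), with SQLE at 0.98. E2F genes fell by -0.21 (43 of 46 lower, adjusted p = 0.0086, adjusted p = 0.614 with an estimated correlation), with ORC1 at -0.59, and G2/M genes by -0.25 (41 of 50 lower; 0.015, 0.653), with CCNA2 at -0.73. Neither passed without hairpin #10 (-0.11 and -0.16). Without hairpin #3, G2/M genes (-0.21), CDKs, cyclins and CDK inhibitors (0.06) and p53 targets (0.18) did not pass. Granulocyte, monocyte, and eosinophil, basophil and mast cell genes passed without hairpin #1 (0.26, 0.28 and 0.56). With scramble of day 2 in place of the array labelled scramble at day 5, their medians were 0.32, 0.54 and 0.59. Heat shock genes then stood at -0.37 and redox genes at -0.21. That replacement mixes the day with the knockdown. The array labelled scramble at day 5 itself differed from scramble at day 2 by 0.32, 0.31 and 0.22 for the first 3 lists. For heat shock and redox genes it differed by -0.12 and 0.00. Lymphoid genes (-0.24) and fibroblast and epithelial genes (-0.32) passed without hairpin #10. G2/M genes did not pass with no filter (-0.25, adjusted p = 0.070), nor CDKs, cyclins and CDK inhibitors with the mean of a gene's probe sets (0.11, 0.117). Granulocyte genes passed after quantile normalization (0.11), with no filter (0.13) and with the mean of probe sets (0.16), eosinophil, basophil and mast cell genes after quantile normalization (0.39) and lymphoid genes after median centring (-0.14). The other 9 lists did not pass, among them monocyte and macrophage genes at 0.22, where CD14 stood at 3.03 (SE 1.61) from a signal of 5.15 in the array labelled scramble at day 5, and granulocyte maturation genes at 0.15 (adjusted p = 0.050). Erythroid and megakaryocyte genes had a median of -0.29 and a mean of 0.00. No list had a member called over all genes or adjusted over the list alone.

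Over both days, with each construct averaged to 1 value (3 hairpins and scramble), no gene passed. The genes higher by most in their least-moved hairpin were PLIN2 at 2.17 (SE 0.82), MMP9 at 1.72 (SE 0.60), PHLDA1 at 1.71, VLDLR at 1.93, SEL1L3 at 1.26, SCARB2 at 1.90, the GTPase gene RRAGD at 0.95, STK17B at 1.08, SCAPER at 1.26 and ZFP36L1 at 3.18. Those lower by most were FAM98A at -0.80 (SE 0.26), the fatty acid elongase gene ELOVL3 at -0.80, the sphingolipid transporter gene SPNS2 at -0.77, PUSL1 at -0.81, SNHG9 at -0.48, ARHGDIA at -0.94, TANGO2 at -0.57, IFRD2 at -0.76, ELOA at -0.82 and SCARB1 at -0.62. Each had 1 sign in all 6 hairpin arrays, the array labelled shCDK2 #3 at day 2 included. In limma 0 genes were called and 109 had an unadjusted p under 0.05 (chance gives 642). Without hairpin #10, hairpins #1 and #3 stood against the single scramble value, with PLIN2 at 1.54 and ZFP36L1 at 2.14. The spread in that fit leaned on that of all genes, so a call there does not mean that #1 and #3 moved alike. ZFP36L1 stood at 3.48 in #3, and its least-moved array among all hairpins stood at 0.54.

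By list, over both days interferon genes rose by 0.84 (adjusted p = 9.23e-11, adjusted p = 0.601 with an estimated correlation), NF-kB genes by 0.75 (3.79e-09, 0.601), glycolysis genes by 0.17 (1.69e-04, 0.601), cholesterol genes by 0.18 (4.08e-04, 0.601) and granulocyte maturation genes by 0.20 (0.0026, 0.601). The granulocyte rise was not shared by all arrays, and 2 of its 29 genes were higher in every hairpin array. Its median was 0.12 in #1 at day 2 and -0.22 in #1 at day 5. It was 0.02 in the array labelled shCDK2 #3 at day 2, 0.42 in #3 at day 5, and 0.68 and 0.20 in #10. Eosinophil, basophil and mast cell genes rose by 0.46 (adjusted p = 0.0068, adjusted p = 0.601 with an estimated correlation), stress response genes by 0.08 (0.013, 0.601), monocyte and macrophage genes by 0.20 (0.017, 0.601), apoptosis regulators by 0.11 (0.021, 0.601) and p53 targets by 0.15 (0.031, 0.601). E2F genes fell by -0.28 (42 of 46 lower, adjusted p = 1.1e-06, adjusted p = 0.601 with an estimated correlation), with CDC25A at -0.65 (SE 0.37) and UHRF1 at -0.60. G2/M genes fell by -0.21 (45 of 50 lower, adjusted p = 2.11e-04, adjusted p = 0.650 with an estimated correlation), heat shock genes by -0.27 (0.0086, 0.601) and redox genes by -0.15 (0.031, 0.601), the last with SLC7A11, a cystine transporter gene, at -0.85. Without hairpin #1 p53 targets did not pass (0.20), and without hairpin #3 stress response (0.08) and redox genes (-0.14) did not, while promyelocyte and progenitor genes did (-0.15). With the mean of a gene's probe sets apoptosis regulators turned to -0.01 (adjusted p = 0.275) and neither they nor stress response genes (0.06, 0.067) or redox genes (-0.12, 0.211) passed. After quantile normalization monocyte and macrophage genes (0.18, adjusted p = 0.053) and redox genes (-0.13, 0.053) did not pass, nor did redox genes with no filter (-0.12, 0.062). The other 5 lists did not pass, and no list had a called member by either count. Medians and means differed in sign for lymphoid genes (-0.07 and 0.03), CDKs, cyclins and CDK inhibitors (-0.03 and 0.13) and erythroid and megakaryocyte genes (-0.11 and 0.10).

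Between day 2 and day 5 in the hairpin arrays, no gene passed. The genes higher by most in their least-moved hairpin were the complement gene C3 at 3.21 (SE 0.89), the chemokine genes CCL2 at 2.92 (SE 0.88) and CCL3 at 2.86, the lymphotoxin gene LTB at 1.34 (SE 0.18), NFKBIA at 1.61 (SE 0.41), SGK1 at 2.64, THBS1 at 2.66, MMP9 at 1.75, JUN at 1.71 and SUSD6 at 1.72. Those lower by most were PROK2 at -1.37 (SE 0.20), TNKS2 at -1.43, MOK at -0.88, HIRA at -0.91, DIAPH1 at -0.65, RRAGD at -0.93, NXF3 at -0.70, TIFA at -0.64, STAR at -0.62 and TET1 at -0.51. In limma 0 genes were called and 260 had an unadjusted p under 0.05 (chance gives 642). NF-kB genes rose by a median of 1.42 (22 of 24 higher, 18 in every hairpin, adjusted p = 3.42e-22, adjusted p = 0.666 with an estimated correlation), and 0 members passed over all genes and 4 adjusted over the list alone, with NFKBIE at 0.82 (SE 0.14) and TNF at 1.02 (SE 0.17) among them. Interferon genes rose by 0.94 (adjusted p = 4.52e-13, adjusted p = 0.701 with an estimated correlation), stress response genes by 0.17 (3.86e-04, 0.701), monocyte and macrophage genes by 0.37 (0.0017, 0.701) with CD163 at 2.82 from signals of 4.70 to 4.88 at day 2, and apoptosis regulators by 0.22 (0.0072, 0.701). Without hairpin #3 monocyte and macrophage genes (0.21) and apoptosis regulators (-0.02) did not pass, and without hairpin #10 stress response genes (0.10) did not. Granulocyte maturation genes, at 0.19, passed without hairpin #1 (0.28) or without hairpin #10 (0.28), and with no filter (0.08). Cholesterol genes, at -0.06, passed downward without hairpin #1 (-0.24) and upward without hairpin #3 (0.19). The other 14 lists did not pass, with E2F at -0.06, G2/M at -0.04 and glycolysis at -0.03.

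In scramble, the array labelled scramble at day 5 against scramble at day 2 gave 0 called genes in limma and 188 at an unadjusted p under 0.05, 17 higher and 171 lower. CDK2 stood at -0.91 (SE 0.65) in this pair, granulocyte maturation genes at a median of 0.32, NF-kB genes at 0.27 and E2F genes at -0.13. Lists of other cell types were higher too. Monocyte and macrophage genes stood at 0.31, lymphoid genes at 0.28, fibroblast and epithelial genes at 0.25 and erythroid and megakaryocyte genes at 0.24. Eosinophil, basophil and mast cell genes stood at 0.22, and promyelocyte and progenitor genes at -0.25. The knockdown change at day 5 minus that at day 2 also passed for 0 genes, with 164 at an unadjusted p under 0.05, 130 higher and 34 lower, and CDK2 at 0.69 (SE 0.75). Chance gives 642 genes at that threshold, more than in either comparison.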

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

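The tests of the size of the CDK2 loss, of hypoxia-inducible genes, of a single faulty CDK2 probe set and of the lone construct were chosen after the result was seen. So were the differences between hairpins and the list tests of the knockdown change at day 5 minus that at day 2.

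Hairpins #10 and #1 differed in 42 genes, 41 higher in #10 and PIR lower, and a difference between these groups by a test of the difference itself singled this out. A larger loss of CDK2 mRNA in #10 cannot be told apart from an equal loss: CDK2 differed by -0.018 log2, with an interval from -1 to 0.96 that is too wide to decide. Low oxygen or a crowded culture also stays open: a list of hypoxia-inducible genes stood at 1.52 in the lower of the #10 arrays and at most at 0.10 in #1, which at percentile 99.5 of matched random lists went against the prediction for #1. The random lists were matched on signal alone, not on how genes move together, so extreme percentiles come easily. In #1 at day 5 granulocyte maturation genes stood at percentile 0.01 and cholesterol genes at 100, while 0 lists passed camera in #1. The hypoxia-inducible list was written after the data were seen and 10 of its 24 tested members, SPAG4 and BNIP3 among them, were themselves called in #10, so it partly restates the pattern and decides nothing. Off-target effects of hairpin #10, the dose of virus and CDK2 protein were not tested.

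In the array labelled shCDK2 #3 at day 2 CDK2 stood at 95%, 80.5% and 108% of scramble on its 3 probe sets, against 39.9%, 28.1% and 79.7% in #1, and in the array labelled scramble at day 5 it was lower than in scramble at day 2 on 2 of them. A single faulty probe set is argued against for the array labelled scramble at day 5, where 2 of 3 probe sets were lower by over 0.5 log2. An exchange of the 2 arrays stays open: across genes, with genes not independent replicates, the change of the 1 array from the other had r = 0.087 with #3 at day 5 minus scramble at day 2, between the -0.11 of hairpin #1 and the 0.61 of #10 built the same way. The prediction written for an exchange was a negative r, which was not met, but 0.087 also fell short of the value set beforehand as going against it. The day enters both differences, and it raises r under an exchange and lowers it without one. The sign of r therefore cannot decide, and hairpin #1, whose arrays were not in question, had a negative r. A slower cell cycle of the scramble cells at day 5 stays open too, with E2F and DNA replication genes at a median of -0.13 (interval over genes -0.22 to -0.03). A mislabelling of a single array was not tested.

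Between the shCDK2 arrays of day 5 and day 2, 260 genes had an unadjusted p under 0.05 in limma, fewer than the 642 that chance gives. Of the 10 splits of the 6 arrays, 6 gave as many. The splits are too few for a share under 0.05, and the highest other split gave 3754, with 699 at adjusted p under 0.05. That split set #1 at both days and the array labelled shCDK2 #3 at day 2 against #10 at both days and #3 at day 5, and it points to a structure of the samples. For the knockdown over both days, all 4 choices of the lone construct gave at least the 109 genes of scramble, with 1450 for hairpin #10, and 4 choices are too few for a share under 0.05.

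The knockdown change at day 5 minus that at day 2, which rests on the array labelled shCDK2 #3 at day 2 and the array labelled scramble at day 5, was singled out by a test of the difference for 7 lists. NF-kB genes differed by a median of 1.22 (camera, adjusted p = 1.23e-04, adjusted p = 0.544 with an estimated correlation), interferon genes by 0.86 (0.0026, 0.829) and heat shock genes by 0.38 (0.0092, 0.544). CDKs, cyclins and CDK inhibitors differed by 0.25 (adjusted p = 0.035, adjusted p = 0.544 with an estimated correlation), stress response genes by 0.23 (0.0026, 0.544), fibroblast and epithelial genes by -0.30 (0.019, 0.544) and lymphoid genes by -0.35 (0.0031, 0.544). The fibroblast and lymphoid lists were dim (median signals 6.67 and 6.90). In the array labelled scramble at day 5 they stood 0.25 and 0.28 higher than in scramble at day 2.

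Opposite signs in every hairpin at day 2 and at day 5 singled out 5 genes and 3 lists. In the limma test of the difference no gene passed (adjusted p = 1.00 each), and the difference of the mean changes was 2.68 log2 for CPOX, 1.33 for FDXACB1, -1.55 for TNKS2, -0.76 for DIAPH1 and -0.59 for NXF3. The mean of the array medians differed by 0.20 for CDKs, cyclins and CDK inhibitors, -0.37 for lymphoid genes and -0.33 for erythroid and megakaryocyte genes, of which the last did not pass camera (adjusted p = 0.070, adjusted p = 0.544 with an estimated correlation).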

How the results depend on the processing

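Leaving out the array labelled shCDK2 #3 at day 2 or the array labelled scramble at day 5 was chosen after the data were seen. The counts of called genes and CDK2 levels of the comparisons were unchanged in call in 193 of their alternatives, 6 became stronger, 5 weaker and 0 reversed. Among lists, judged by the direction of the camera test, 606 were unchanged, 27 stronger, 48 weaker and 3 reversed, and among named genes 1309, 16, 49 and 0. A result past no threshold in both fits counted as unchanged, and a count of genes could not be reversed. In the main fit no named gene passed outside hairpins #3 and #10, so most unchanged genes were uncalled throughout. These tallies therefore do not measure how stable the calls were. Median centring alone weakened 16 named genes. The count for hairpin #10 was 82 after median centring, 960 without the array labelled shCDK2 #3 at day 2, 0 without the array labelled scramble at day 5, and 354 to 960 with another hairpin left out. That for hairpin #3 was 0 after median centring, 0 with the mean of all probe sets of a gene, 213 without the array labelled shCDK2 #3 at day 2, 0 without the array labelled scramble at day 5, and 9 to 27 with another hairpin left out. The count over both days was 0 to 11 with a hairpin left out. Leaving out an array also leaves fewer samples, yet some counts rose. The count for #10 was the same without hairpin #3 and without only the array labelled shCDK2 #3 at day 2. Either way the difference between the 2 arrays of #3 leaves the spread pooled over constructs. A construct left with 1 array was assumed to vary like the others. Beyond that the cause was not tested.

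Cholesterol biosynthesis genes reversed at day 2 without hairpin #3 (-0.051) and without the array labelled shCDK2 #3 at day 2 (-0.051), with a range from -0.051 to 0.44 over the hairpins left out. In 5 cases where a list lost its call and 1 where a list gained one, the median changed sign while the test direction did not. These were apoptosis regulators over both days with the mean of all probe sets of a gene (-0.01) and for day 5 against day 2 without hairpin #3 (-0.02). With scramble at day 2 in place of the array labelled scramble at day 5 they were CDKs, cyclins and CDK inhibitors (-0.04) and p53 targets (-0.01) at day 5. Without the array labelled scramble at day 5 they were apoptosis regulators in #3 (-0.02) and lymphoid genes in #10 (0.17, which gained the call). For day 5 against day 2 cholesterol genes ranged from -0.24 to 0.19, with 0.19 without hairpin #3. The cause was not tested. CDK2 ranged over all alternatives from -1.44 to -0.23 log2 at day 2, -1.20 to -0.20 at day 5 and -1.31 to -0.23 over both days, and passed in none. The -1.20 sets the hairpins at day 5 against scramble at day 2, and the -1.31 leaves out the array labelled shCDK2 #3 at day 2 and the array labelled scramble at day 5, so both mix the day with the knockdown.

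With the construct as a replicate block the counts stayed 0, at a consensus correlation of 0.275. The labels do not say that a construct's arrays of different days came from 1 culture. For a check, the mean of a day's 3 hairpin arrays was subtracted from each gene. On these deviations only #1 at day 2 and at day 5 correlated best with itself both ways (r 0.72). The r was -0.23 within #3 and 0.43 within #10, with 0.57 between #10 at day 2 and #3 at day 5. Deviations within a day sum to 0, so the r of #1 can reflect the other hairpins lying opposite to it. As changes from scramble, #1 had an r of -0.07 with itself. Genes with a mean under 5.83 log2 were not tested, and changes close to background are compressed. The alternatives for linear values were not run, since the values are on a log scale.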

Other observations

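The list of hypoxia-inducible genes and its comparison with interferon genes were chosen after the result was seen.

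Hypoxia-inducible genes, of which 24 were tested and 10 were among the genes called in hairpin #10, had a median change from scramble of 1.52 log2 in hairpin #10 at day 2 and 1.78 at day 5, and 1.48 in #3 at day 5. Camera was not run on this list. In the array labelled shCDK2 #3 at day 2 the median was 0.71, and in hairpin #1 it was 0.07 at day 2 and 0.10 at day 5, at percentiles 96.6 and 99.5 of matched random lists. The array labelled scramble at day 5 stood at -0.40 against scramble at day 2. In the array labelled shCDK2 #3 at day 2 interferon genes had a median of 0.12, while in #10 at day 2 they stood at 1.00. Among the genes that differed between #10 and #1 were also the lipid droplet gene HILPDA at 2.83, the G protein signalling regulator gene RGS1 at 2.80 and the vasodilator peptide gene ADM at 2.01.

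Hairpin #3 at day 5 stood apart in scale, with the lowest bioB spike-in mean (8.67, against 9.02 to 9.37 in the others), the lowest median (6.30) and the highest standard deviation (2.26). The log2 signal of the 3' minus the 5' probe set lay between 1.55 and 2.06 for ACTB and between 0.51 and 0.75 for GAPDH, and the correlation of arrays across probe sets lay between 0.964 and 0.994. The ACTB value of 2.06 was that of scramble at day 2, against 1.65, 1.68 and 1.55 in the hairpin arrays of that day. For GAPDH these were 0.67 against 0.66, 0.55 and 0.51. At day 5 ACTB stood at 1.68 in scramble against 1.84, 1.69 and 1.83. Whether this bears on the changes at day 2 was not tested.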
